A study of Mus musculus with 42 samples.

How the data were processed

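T-cell receptor beta (TCRβ) transcripts were sequenced from T cells sorted out of thymus, spleen and lung of mice in which Foxn1-Cre, active in thymic epithelial cells, met a floxed allele of NIK, the NF-κB-inducing kinase. Per the labels, the mice called WT carried 1 floxed and 1 intact NIK allele and the mice called KO carried 2 floxed alleles, so WT here means a heterozygous floxed control. Conventional CD4 and CD8 T cells were gated as CD25-negative and CD62L-positive, and regulatory T cells (Tregs) as CD4-positive with high CD25. RNA was taken from cells sorted into lysis buffer and turned into libraries with a mouse TCR a/b profiling kit, per the labels' protocols. Sequences were referred to the mouse build mm10, per the submitters' processing notes. The aligner, the clonotype caller, error correction and any filter on reads are not given in the sources used here. The series lists 42 samples in 14 groups from 6 mice. Processed files of 5 libraries were used, each from another group, and the other 37 samples were not analysed here.

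Each deposited file is a clonotype table holding the read count, the fraction of reads, the CDR3 nucleotide and amino acid sequence, the V, D and J segment and the positions where they end and start. The deposited values are raw read counts per CDR3 nucleotide sequence, per the file headers and the values, which are whole numbers that sum to another total in each file. The deposited fraction of each clonotype equalled its count divided by the file's total and summed to 1 in each file, so no clonotype had been removed after that column was made. The positions at segment ends are other values in bases, per the file headers. The files held β chains alone, so the α rearrangements of natural killer T (NKT) cells and mucosal-associated invariant T (MAIT) cells, planned as markers of other cells in the gates, were not run. All 44 segment names in the files were found among the RefSeq symbols of the same mouse build, GRCm38.p6, which gave coordinates and gene status.

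A clonotype was a distinct CDR3 nucleotide sequence with its V and J segment, and a productive clonotype had a CDR3 in frame without a stop codon. Reads are PCR copies with no molecular identifier stated, so segment usage was counted per productive clonotype and not per read. Shares carry exact Clopper-Pearson 95% intervals. Ratios of shares carry 95% log intervals, and a segment was called higher or lower between 2 libraries if the ratio was at least 1.25 or at most 0.8 and the interval left out 1. Differences of means carry 95% bootstrap intervals over clonotypes from 1000 draws. Diversity was computed in 100 random draws of 96229 reads, the productive reads of the smallest library, with the SD over draws. The ratios of inverse Simpson indices, and the SD used to judge changes in diversity ratios, came from a separate set with fewer draws. Clonotype sharing was scaled to 1724 clonotypes per library, the number in the smallest library. All intervals cover counting error only. With 1 library per group they compare libraries and not genotypes, lineages or organs, and no test of a condition was made.

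CDR3 positions were counted from the conserved Cys as position 1. Hydrophobic pairs at positions 6 and 7 were those with both residues among I, L, V, F, M, W, Y and C, over clonotypes starting with Cys and at least 8 residues long. Net charge was summed over the residues between the first 4 and the last 4. After the data had been seen, a standard CDR3 was defined as one that starts with Cys, ends with Phe and is 8 to 20 residues long, because the caller had placed some CDR3 starts far upstream. A germline stretch of 22 bases just before the second D segment, TGTATCACGATGTAACATTGTG, was used to find sequences that had not joined a V segment. Inserted bases were those between the V, D and J ends listed in the files. Where no D segment was listed, all bases between the V and J ends were counted, which may include bases of a D segment. The share of clonotypes with no D segment listed was not compared between libraries.

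The segments named were fixed before the data were examined: for each of the 4 comparisons, those with at least 1% of productive clonotypes in either library that were called, at most 12 per direction. Named whether called or not were the segments whose β chains bind superantigens of endogenous retroviruses, those favoured by NKT and MAIT cells, the TRBJ1 and TRBJ2 clusters, the 3 leading clonotypes of each library and up to 5 clonotypes found in most libraries. The alternatives planned at the same time were a minimum of 2 reads per clonotype, amino acid clonotypes, reads as weights, equal depth, a smaller draw, a mean hydropathy score, other rules for sharing, and a minimum of 10 reads for sharing. Restriction to standard CDR3s and removal of clonotypes 1 base away from one with at least 10 times the reads were added after seeing the data. So was removal of sequences that had not joined a V segment.

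The segment calls were tested on simulated libraries with the real numbers of clonotypes, 200 for each comparison. With no difference simulated, the mean number of false calls was 0.57 over 29 segments for spleen CD8 KO against WT. Over 26 segments it was 1.04 for KO spleen CD8 against CD4, 1.06 for lung against spleen CD4 and 1.03 for Treg against spleen CD4. These numbers include segments under 1%, which the counts of named segments leave out. A change of 1.5 times was recovered in 92.8%, 67.4%, 71.5% and 74.4% of segments in the same order, and a change of 2 times in 99.4%, 91.3%, 93.5% and 94.6%. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Depth ran from 98655 to 205882 reads per library, and a segment with 0 of the productive clonotypes could still hold a share of up to 0.018% in the WT CD8 library and up to 0.174% in the KO spleen CD4 library, which is 3 counts of each total.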

Results

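The series asked how NIK in the thymic epithelium shapes the T cells that the thymus sends out. TCRβ repertoires of 5 libraries were compared: spleen CD8 T cells of WT mouse 614 and KO mouse 617, spleen CD4 T cells of KO mouse 597, lung CD4 T cells of KO mouse 617 and thymus Tregs of KO mouse 618. From each group 1 library was analysed, so no value has a replicate. The floxed gene is not read by this assay and its deletion lies outside T cells, so the genotype labels could not be checked in these files. The files held 157688 reads for WT spleen CD8, 194834 for KO spleen CD8, 98655 for KO spleen CD4, 140826 for KO lung CD4 and 205882 for KO thymus Treg. Productive clonotypes numbered 16703, 2644, 1724, 3354 and 3761 in that order, and they held between 96.1% and 98.2% of the reads. Out-of-frame or stop-containing clonotypes made up 7.81% (95% interval 7.42 to 8.21) of the WT CD8 clonotypes, 13.9% (12.7 to 15.2) in KO CD8, 15.3% (13.7 to 16.9) in KO spleen CD4, 13.1% (12.1 to 14.2) in KO lung CD4 and 16.2% (15.2 to 17.3) in KO Treg. By number they were 1415, 428, 311, 507 and 729 in the same order.

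The spleen CD8 comparison set the KO library against the WT library, which was the sole pair that differed in genotype. The KO library held 0.158 times as many productive clonotypes as the WT library, and its repertoire was dominated by a few clones. In KO CD8 cells the 10 leading clonotypes took 39.0% of productive reads and 17 clonotypes sufficed for 50% of them, against 1.62% and 3012 clonotypes in WT CD8 cells. The leading KO clonotypes were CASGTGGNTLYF (TRBV16, TRBJ2-4) with 7.67% of productive reads, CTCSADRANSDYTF (TRBV1, TRBJ1-2) with 6.86% and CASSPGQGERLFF (TRBV12-2, TRBJ1-4) with 5.07%. The WT library was led by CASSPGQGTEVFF (TRBV5, TRBJ1-1) with 0.667%, followed by the short fragment YAEQFF (TRBV21, TRBJ2-1) with 0.151% and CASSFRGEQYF (TRBV14, TRBJ2-7) with 0.133%. Of these 6 clonotypes, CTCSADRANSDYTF and YAEQFF were present in both CD8 libraries, with 94 and 233 reads in WT and 13125 and 328 in KO. At 96229 reads, 15390 ± 24.7 clonotypes (SD over draws) were seen in WT and 2320 ± 13.5 in KO. The inverse Simpson index was 5461 ± 64.3 in WT and 45.0 ± 0.222 in KO. A separate set with fewer draws gave a ratio of 0.00823, and of 0.0124 in a smaller draw of reads.

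**Figure D1:**
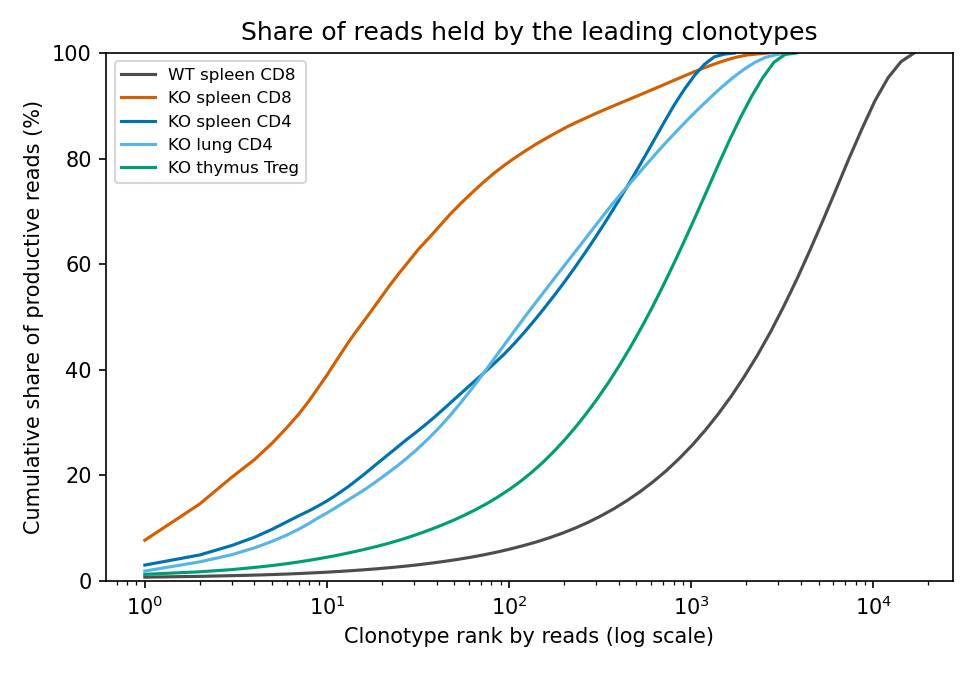
Cumulative share of productive reads (%, vertical axis) held by clonotypes ranked by reads (log scale, horizontal axis), 1 line per library. The KO spleen CD8 line reaches 39.0% at rank 10 and 79.4% at rank 100, where the WT spleen CD8 line is at 1.62% and 5.95%.

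Few V segments differed between the KO and WT spleen CD8 libraries. Of 19 TRBV segments with at least 1% of productive clonotypes, 1 was called higher in KO and 2 were called lower. TRBV22 was higher (1.97% against 1.26%, ratio 1.56, interval 1.16 to 2.11), while TRBV29 (Vβ7; 3.56% against 5.05%, ratio 0.704, 0.571 to 0.867) and TRBV12-1 (a Vβ5 segment; 3.63% against 4.56%, ratio 0.796, 0.646 to 0.98) were lower. Of the 10 superantigen-binding segments these last 2 were called lower and 8 were not called; the group made up 51.8% of KO and 52.6% of WT clonotypes (ratio 0.984, 0.946 to 1.02). Its most used members were TRBV16 (Vβ11) at 10.9% and 9.75% and TRBV12-2 (Vβ5) at 9.91% and 9.18%. The group favoured by NKT cells, TRBV13-2, TRBV29 and TRBV1, took 18.8% and 19.5%, and the group favoured by MAIT cells, TRBV19, TRBV13-2 and TRBV13-3, took 21.2% and 21.3%; neither was called. TRBJ1-1 (10.6% against 8.04%, ratio 1.32, 1.17 to 1.49) and TRBJ1-3 (5.98% against 4.51%, ratio 1.32, 1.12 to 1.56) were higher in KO, and the TRBJ1 cluster as a whole was at 34.2% against 30.02% (ratio 1.14, 1.08 to 1.21, not called). The annotation lists both TRBV22 and TRBV29 as pseudogenes. The call of TRBV29 was kept among standard CDR3s, with at least 2 reads and at equal depth, while that of TRBV12-1 was lost in all 3 (0.806, 0.802 and 0.818) and that of TRBV22 among standard CDR3s (1.12, 0.743 to 1.7) and at equal depth (1.38, 0.973 to 1.95). Weighted by reads, the ratio of TRBV22 turned to 0.576 and that of TRBJ1-1 to 0.494, while that of TRBV12-1 was 0.157 and that of TRBJ1-3 was 1.13.

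CDR3s with hydrophobic residues at both positions 6 and 7, a feature known to favour self-reactivity, were rarer in the KO than in the WT CD8 library, at 0.514% (13 of 2527) against 0.992% (160 of 16132). The ratio was 0.519 (0.295 to 0.911), and 0.088 with reads as weights. Cysteine anywhere between the ends was found in 10.7% of KO and 8.72% of WT clonotypes (ratio 1.23, 1.09 to 1.39, not called; 1.9 with reads as weights). Of those clonotypes 58.1% in KO and 63.1% in WT carried TRBV1, whose germline end gives CTCS, and a further 35.6% and 32.8% were not standard CDR3s. In the middle of standard CDR3s, where cysteine is a known feature of strongly self-reactive receptors, it was found in 12 of 2505 KO and 25 of 16038 WT clonotypes, 0.479% against 0.156% (ratio 3.07, 1.55 to 6.11). Mean CDR3 length was 14.2 residues in KO and 14.0 in WT over productive clonotypes (difference 0.199, 0.000284 to 0.417), but 13.2 against 13.4 among standard CDR3s (difference -0.103, -0.162 to -0.0403). The difference was 0.0641 (-0.116 to 0.242) with at least 2 reads, 0.046 (-0.13 to 0.234) at equal depth and -0.331 with reads as weights. Mean net charge was -0.479 in KO and -0.5 in WT (difference 0.0208, -0.0182 to 0.0607). The mean hydropathy of positions 6 and 7 did not separate the libraries (difference -0.0295, -0.0924 to 0.0323), and the 13 KO clonotypes limit the precision of the hydrophobic share.

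CD8 and CD4 T cells from KO spleen differed more in V segment usage than any other of the 4 pairs by number of calls, with 7 TRBV segments higher and 8 lower in CD8 among 22 with at least 1%. Highest in CD8 relative to CD4 was TRBV29 (3.56% against 1.1%, ratio 3.23, 1.98 to 5.26), followed by TRBV14 (4.43% against 1.74%, ratio 2.54), TRBV12-2 (9.91% against 4.87%, ratio 2.03), TRBV17 (Vβ9; 5.33% against 2.73%, ratio 1.96), TRBV13-1 (6.66% against 3.42%, ratio 1.95), TRBV16 (10.9% against 6.21%, ratio 1.76) and TRBV12-1 (3.63% against 2.32%, ratio 1.56). Lower in CD8 were TRBV2 (1.74% against 6.09%, ratio 0.286, 0.203 to 0.402), TRBV22 (1.97% against 6.21%, ratio 0.317), TRBV23 (0.391), TRBV24 (Vβ17; 0.404), TRBV15 (Vβ12; 0.603), TRBV5 (0.624), TRBV3 (0.662) and TRBV19 (Vβ6; 0.782), with the ratio in parentheses. All 15 calls were kept among standard CDR3s. There, 24 of 26 clonotypes listed under TRBV22 in CD8 and 76 of 79 in CD4 start CAW. Whether these come from TRBV22 or are misnamed is left open further below. In the WT CD8 library TRBV2 stood at 1.56% and TRBV29 at 5.05%. The pair came from mice 617 and 597, so lineage and mouse differ together.

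**Figure D2:**
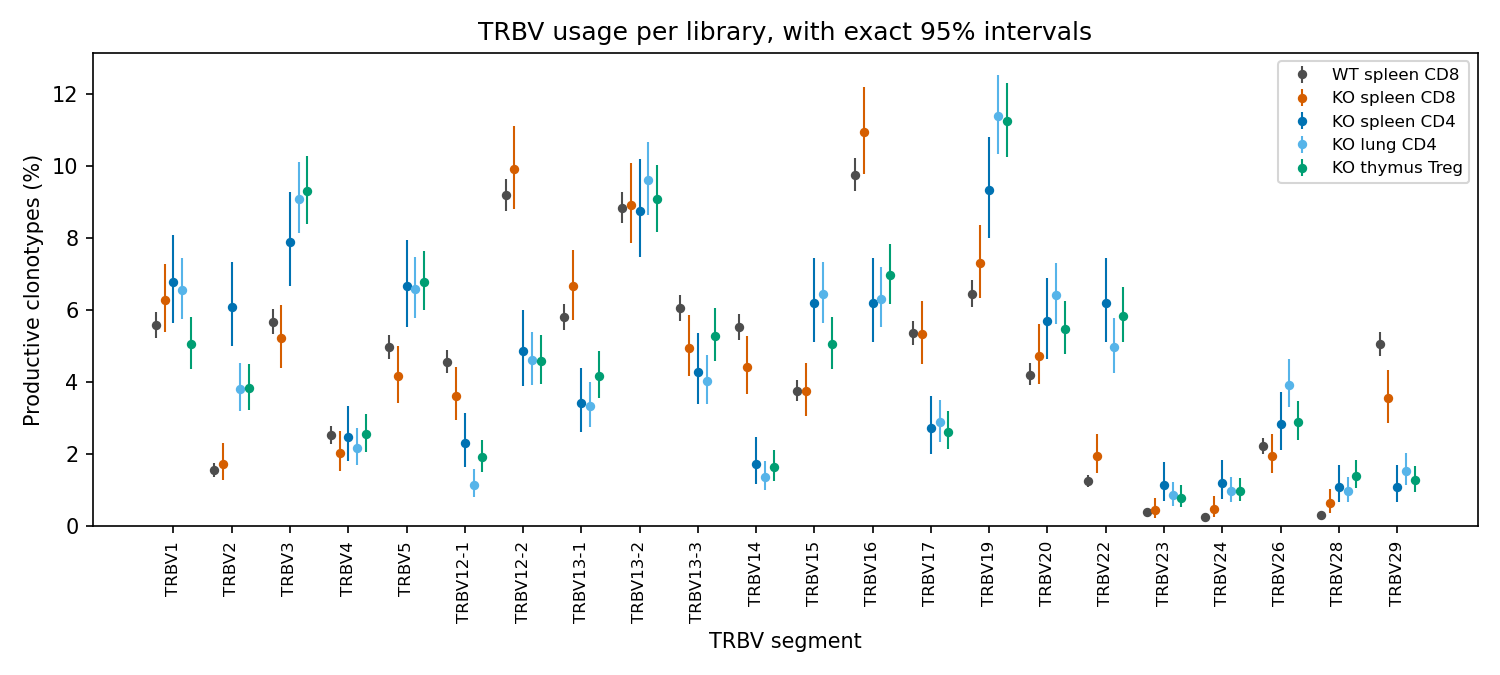
Share of productive clonotypes (%, vertical axis) for each TRBV segment that reached 1% in at least 1 library (horizontal axis), 1 point per library with its exact 95% interval for counting error. TRBV2 stands at 1.56% and 1.74% in the CD8 libraries and between 3.82% and 6.09% in the CD4 and Treg libraries.

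The superantigen-binding group was higher in KO spleen CD8 than CD4 cells, at 51.8% against 41.1% (ratio 1.26, 1.18 to 1.35). Of its 10 members, 5 were higher, 3 were lower and 2, TRBV13-3 (4.95% against 4.29%) and TRBV26 (Vβ3; 1.97% against 2.84%), were not called. The NKT-favoured group was at 18.8% against 16.6% and the MAIT-favoured group at 21.2% against 22.4%, neither called; TRBV13-2 (Vβ8.2) was at 8.93% and 8.76% and TRBV1 (Vβ2) at 6.28% and 6.79%. TRBJ2-1 (15.8% against 10.5%, ratio 1.5) and TRBJ1-1 (10.6% against 7.37%, ratio 1.44) were higher in CD8, and TRBJ2-4 (ratio 0.707), TRBJ1-4 (0.744), TRBJ2-5 (0.792) and TRBJ1-3 (0.799) were lower, with the call of TRBJ2-5 lost among standard CDR3s (0.811) and at equal depth (0.803). The TRBJ1 cluster stood at 34.2% and 33.9%. Hydrophobic pairs at positions 6 and 7 were at 0.514% and 0.741% (ratio 0.694, 0.318 to 1.52; 0.261 with reads as weights), not distinguishable at 13 and 12 clonotypes. Cysteine was found in 10.7% and 12.9% (ratio 0.834, 0.707 to 0.984, not called), while in the middle of standard CDR3s the ratio was 2.57 (0.726 to 9.09, 12 and 3 clonotypes). Net charge was less negative in CD8 (-0.479 against -0.574, difference 0.0948, 0.037 to 0.154), but not separable among standard CDR3s (difference 0.0295, -0.0183 to 0.0803), and the difference was 0.0234 with reads as weights. CDR3 length differed by -0.341 residues, CD8 minus CD4, over productive clonotypes, with an interval from -0.685 to 0.00287. At equal depth it was -0.547 and cleared 0 (-0.905 to -0.192), with reads as weights it was -0.177, and among standard CDR3s the CD8 CDR3s were longer (difference 0.15, 0.0668 to 0.235). The KO spleen CD4 library was led by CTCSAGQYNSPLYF (TRBV1, TRBJ1-6) with 2.95% of productive reads, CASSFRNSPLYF (TRBV14, TRBJ1-6) with 1.92% and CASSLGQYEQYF (TRBV15, TRBJ2-7) with 1.8%. Weighted by reads, the ratios of TRBV12-1, TRBV13-1 and TRBJ1-1 turned below 1, to 0.463, 0.545 and 0.655, those of TRBJ1-4 and TRBJ2-4 turned above 1, to 1.14 and 1.54, and that of TRBV19 was 0.972. Further from 1 by reads were TRBV12-2 (3.78), TRBV16 (2.93), TRBV22 (0.0613), TRBV23 (0.0303; 0.244 with at least 2 reads) and TRBV24 (0.0391), and nearer to 1 was TRBV14 (1.43).

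KO CD4 cells of lung and spleen differed in few V segments, with 1 TRBV segment higher and 2 lower in lung among 22. TRBV26, the Vβ3 segment, was higher in lung (3.94% against 2.84%, ratio 1.38, 1.003 to 1.91), a call lost with at least 2 reads (1.3, 0.92 to 1.83) and at equal depth (1.38, 0.995 to 1.91). TRBV12-1 (1.16% against 2.32%, ratio 0.501, 0.324 to 0.776) and TRBV2 (3.82% against 6.09%, ratio 0.627, 0.487 to 0.806) were lower. TRBJ1-1 was higher in lung (9.24% against 7.37%, ratio 1.255, 1.03 to 1.53), a call lost among standard CDR3s, and the TRBJ1 cluster stood at 37.1% against 33.9%. The superantigen-binding group was at 43.3% and 41.1% (ratio 1.05, 0.984 to 1.13), with 8 of 10 members not called, among them TRBV19 at 11.4% and 9.34%, TRBV15 at 6.44% and 6.21% and TRBV16 at 6.32% and 6.21%. The NKT-favoured group was at 17.7% and 16.6% and the MAIT-favoured group at 25.01% and 22.4%. The lung library was led by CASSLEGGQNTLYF (TRBV12-1, TRBJ2-4) with 1.82% of productive reads, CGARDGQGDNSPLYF (TRBV20, TRBJ1-6) with 1.74% and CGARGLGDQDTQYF (TRBV20, TRBJ2-5) with 1.35%, and weighted by reads the ratio of TRBV12-1 turned to 2.05, and those of TRBV2, TRBV26 and TRBJ1-1 were 0.912, 2.64 and 1.94. At 96229 reads the lung library held 3172 ± 11.3 clonotypes and the spleen library all of its 1724, with inverse Simpson indices of 289 and 234. CDR3 length (difference -0.00588, -0.357 to 0.37), cysteine (13.1% and 12.9%; in the middle of standard CDR3s ratio 0.86, 0.206 to 3.59), charge (difference 0.00867, -0.0525 to 0.0662) and hydrophobic pairs (0.447% and 0.741%, ratio 0.603, 0.28 to 1.3) did not separate these libraries. With reads as weights the length difference was 0.47, the cysteine ratio 0.591 and the charge difference -0.112. The lung and spleen cells came from mice 617 and 597, and TRBV26 has no standard CDR3 because its CDR3 starts were placed upstream.

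KO thymus Tregs had longer CDR3s than KO spleen CD4 cells, and 2 of 22 V segments were called. Mean length was 14.99 against 14.5 residues over productive clonotypes (difference 0.461, 0.14 to 0.793; at equal depth 0.24, -0.138 to 0.598) and 13.6 against 13.1 among standard CDR3s (difference 0.481, 0.404 to 0.558). TRBV2 (3.83% against 6.09%, ratio 0.629, 0.492 to 0.803) and TRBV1 (5.05% against 6.79%, ratio 0.744, 0.596 to 0.931) were lower in Tregs, and none was called higher. TRBJ2-7 was higher (22.9% against 18.2%, ratio 1.26, 1.12 to 1.41), while TRBJ1-2 (ratio 0.662, 0.514 to 0.852) and TRBJ1-3 (ratio 0.64, 0.514 to 0.796) were lower, and the call of TRBJ2-7 was lost among standard CDR3s (1.23) and with reads as weights (1.21), and that of TRBJ1-2 with reads as weights (0.961), where the ratio of TRBV1 was 0.419. The TRBJ1 cluster was at 29.7% against 33.9% (ratio 0.876, 0.807 to 0.951, not called). None of the 10 superantigen-binding segments was called, and the group was at 42.9% against 41.1%; its members TRBV19 and TRBV17 stood at 11.2% against 9.34% and 2.63% against 2.73%. The NKT-favoured and MAIT-favoured groups were at 15.4% and 25.6% in Tregs.

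**Figure D3:**
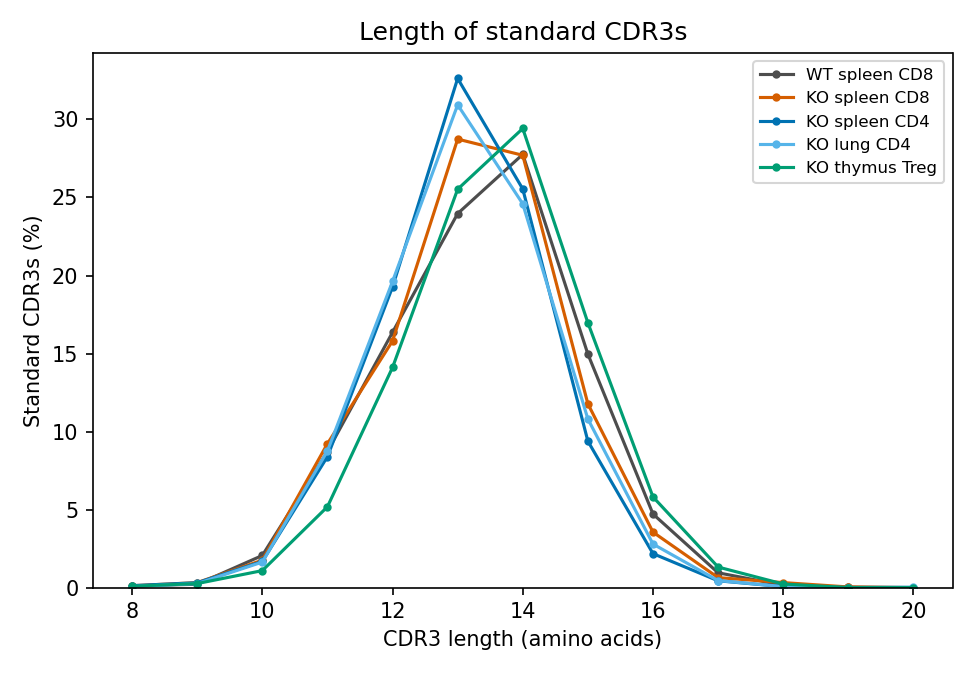
Share of standard CDR3s (%, vertical axis) by length in amino acids (horizontal axis), 1 line per library. The KO thymus Treg line peaks at 14 residues with 29.4%, and the KO spleen CD4 line at 13 residues with 32.6%.

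Hydrophobic pairs at positions 6 and 7 stood at 1.33% (47 of 3522) in Tregs and 0.741% (12 of 1620) in spleen CD4 cells, a ratio of 1.8 whose interval of 0.958 to 3.39 did not leave out 1, and 3.18 with reads as weights. Cysteine was found in 11.01% against 12.9% of clonotypes (ratio 0.855, 0.734 to 0.996, not called; 0.543 with reads as weights), and in the middle of standard CDR3s the ratio was 1.07 (0.278 to 4.15). Net charge was -0.518 against -0.574 (difference 0.0552, -0.00219 to 0.115). The difference cleared 0 with at least 2 reads (0.0804, 0.0182 to 0.14), at equal depth (0.071, 0.0147 to 0.133) and among standard CDR3s (0.0526, 0.000353 to 0.102), and was -0.000482 with reads as weights. The Treg repertoire was the most even of the KO libraries, with an inverse Simpson index of 1193 ± 8.96 and 4.44% of productive reads in its 10 leading clonotypes, against 234 and 15.1% in spleen CD4 cells. Its leading clonotypes were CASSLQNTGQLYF (TRBV15, TRBJ2-2) with 1.2%, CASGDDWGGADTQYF (TRBV13-2, TRBJ2-5) with 0.48% and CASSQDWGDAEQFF (TRBV5, TRBJ2-1) with 0.419%. Lineage, organ and mouse differ together in this pair.

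Scaled to equal clonotype numbers, sharing of productive clonotypes was highest for KO spleen CD8 and KO lung CD4, the sole pair from the same mouse. They shared 216 clonotypes by nucleotide sequence, V and J, which held 17.2% of the CD8 and 13.0% of the lung reads. Scaled to 1724 clonotypes per library this was 72.4 (63.1 to 82.7), while the other 9 pairs had between 6.15 (WT spleen CD8 and KO Treg) and 44.2 (35.4 to 54.6; KO spleen CD4 and KO lung CD4). With at least 10 reads in both libraries these 2 leading pairs shared 66 and 49 clonotypes, and the WT and KO spleen CD8 pair 118. Scaled to 1724 as before, these were 97.8, 68.5 and 52.3. These scaled values extrapolate, since fewer than 1724 clonotypes had 10 reads in KO spleen CD8 (median 8) and KO spleen CD4 (250 with 1 read). Unscaled and with no minimum of reads, the WT and KO spleen CD8 libraries shared more than the 216 of the same-mouse pair. Their 329 shared clonotypes, or 22.1 scaled to 1724 (19.8 to 24.7), held 30.7% of the KO CD8 reads and 3.95% of the WT CD8 reads. WT spleen CD8 and KO lung CD4 also shared more than 216, with 285 clonotypes, or 15.1 scaled to 1724 (13.4 to 17.0). For the same-mouse pair the number shared at the nucleotide level was 84.0% of that at the amino acid level, against 45.6% to 67.0% for the others. In all, 16 sequences were present in every library, of which 2 were standard CDR3s, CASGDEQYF (TRBV13-2, TRBJ2-7) with 158 reads over the 5 libraries and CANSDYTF (TRBV15, TRBJ1-2) with 23. The most read of the other 14 were short or broken, among them YAEQFF with 1778 reads and GAEQFF with 258. Another of the 14, *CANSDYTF with a stop codon, ends in the same bases as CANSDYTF, which may thus be a fragment too.

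**Figure D4:**
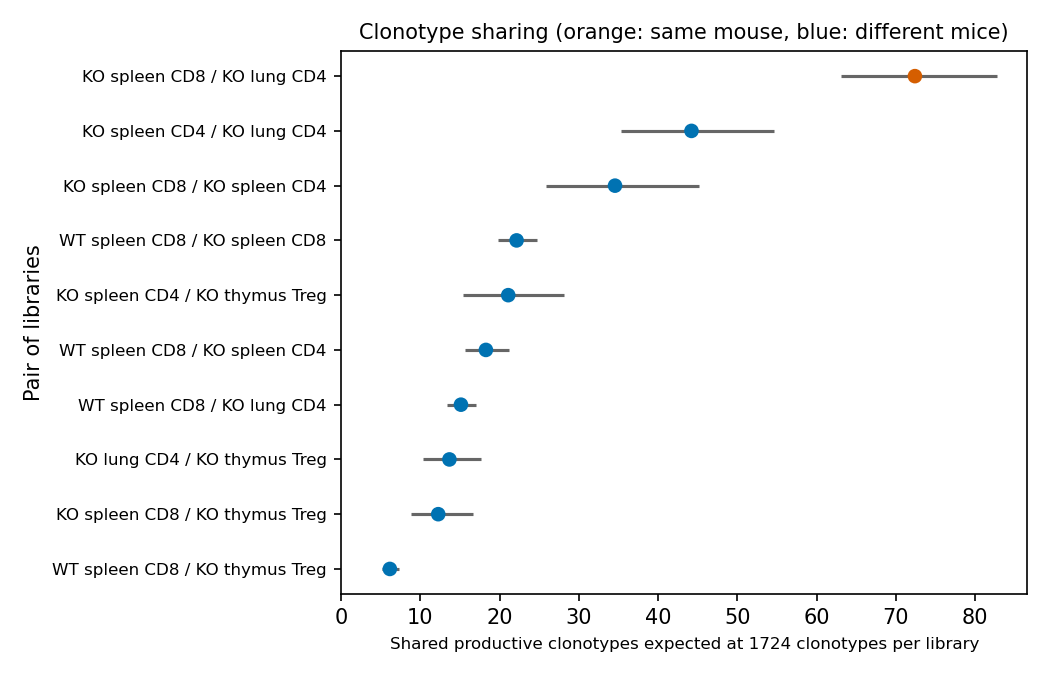
Productive clonotypes shared by each of the 10 pairs of libraries (vertical axis), scaled to 1724 clonotypes per library (horizontal axis), with 95% intervals for counting error. The same-mouse pair, KO spleen CD8 and KO lung CD4, stands at 72.4 and the next pair at 44.2.

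The segments named lie in the Trb locus on chromosome 6 of the mouse build mm10. TRBV2 spans positions 41047556 to 41047995, TRBV29 spans 41271403 to 41271881, TRBV22 spans 41212075 to 41212534 and TRBV26 spans 41227525 to 41227913. TRBJ1-1 lies at 41533864 to 41533911 and TRBJ2-7 at 41543810 to 41543856. The annotation lists TRBV22 and TRBV29 as V segment pseudogenes and the others as V or J segments.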

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

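The comparison at equal reads was planned before the data were examined, but the bound that made it a test of depth was set after its result was seen. The tests of independent recurrence, which replaced one that restated the pattern, and of cells of the other lineage were chosen before their results were seen, and the other tests in this part after. Sequences that keep the germline stretch before the second D segment, and so had not joined a V segment, were present in each library. The comparisons above are meant for receptors with a joined V segment. Productive clonotypes nevertheless include some sequences with the stretch, and short fragments such as YAEQFF. Those with the stretch numbered 103 in WT CD8, 45 in KO CD8, 47 in KO spleen CD4, 62 in lung and 106 in Treg. Sequences with the stretch made up 1.39% of all clonotypes in WT spleen CD8, 5.31% in KO spleen CD8, 6.93% in KO spleen CD4, 4.51% in KO lung CD4 and 6.84% in KO thymus Treg. These shares lay above the limits of 0.0166% to 0.147% that a count of 0 allows. By number the sequences were 252, 163, 141, 174 and 307 in the same order, so the shares also reflect the total of clonotypes. In reads they were rare, from 0.202% to 0.407%. All were listed with a TRBJ2 segment, and 86.5% to 98.0% of them under TRBV22, TRBV27 or TRBV28.

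The call of TRBV22 as higher in KO than WT spleen CD8 cells bears on these sequences. Without them the ratio was 1.18 (0.793 to 1.77) and no longer called. This goes with D-J sequence that had not joined a V segment, listed under TRBV22, as the source of the call. Of 593 TRBV22 clonotypes that start CAW, 85.5% (82.4 to 88.2) were in frame, above the 33.3% of unselected joining and below the 92.2% of segments annotated as functional, so use of the pseudogene itself stays open, since decay of out-of-frame transcripts also raises that share. No clonotype was listed under TRBV31, a functional segment whose CDR3s are known to start CAW, and 52.1% of 972 standard CAW clonotypes were listed under TRBV22. TRBV31 sequences listed under other names may account for this, and without the V sequences in the files that cannot be told apart from other misnaming.

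The low clonotype number and strong dominance in the KO spleen CD8 library were weighed against depth, sequencing errors and cell input. Depth is argued against, since the KO library was the deeper one, with 194834 reads against 157688 in WT. At equal reads it held 0.151 times the clonotypes of WT, a ratio that these read totals left little room to rise. Sequencing errors counted as clonotypes are argued against as well, since removing clonotypes 1 base from a far more abundant one left a ratio of 0.159 (0.153 to 0.166). Fewer sorted cells or less RNA stays open: the sole library with fewer clonotypes, KO spleen CD4, held 15.1% of reads in its 10 leading clonotypes against 39.0%, and 1 library cannot decide it. Genotype and the individual mouse also stay open and untested, because 1 CD8 library of each genotype was analysed.

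The sharing between the spleen CD8 and lung CD4 libraries of mouse 617 was weighed against recurrence, leaking reads and sorting. Independent recurrence of the same sequence is argued against as the whole cause: the 203 standard CDR3s they shared held 0.353 (0.104 to 0.613) more inserted bases on average than the 577 that either library shared with another mouse (1.34 against 0.991). The excess over the next pair was 84.1 clonotypes (44.02 to 124). Leaking at a common rate is argued against as the cause of 84.1, by the number of leading clonotypes found in the other library. Of the 10 leading of each library 3 of 20 (0.641 to 7.58) were found, where such a leak would give 13.1. Of the 50 leading of each, 17 (10.2 to 25.8) were found, where it would give 35.6. A leak that made 44.02 clonotypes, the low end of the excess, stays open. It would give 8.87 of the 10 leading, above that interval, but 20.9 of the 50 leading, within that interval. A weaker leak, or one at uneven rates, stays open as well. Of 3 earlier forms of the test 1 was void, 1 found 1 of 3 abundant clonotypes and 1 was undecided, with 63 (50.1 to 77.1) of the 216 low enough in reads to have leaked. Cells of the other lineage in either sort cannot be told apart from a hypothesis with no further test here, that a TCRβ rearranged before a thymocyte chose its lineage may be present in both, because 34.3% (27.95 to 41.0) of the shared clonotypes used the 7 segments called higher in CD8, between the 44.4% of the CD8 library and the 21.3% of the lung library.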

How the results depend on the processing

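The restrictions to standard CDR3s, to clonotypes without close neighbours and to sequences without the germline stretch were chosen after seeing the data. No paired analysis was possible because 1 library of each group was analysed here. Of 118 recomputed values for the main results, 78 were counted as unchanged, and the cause of the changes below was not tested unless stated. A count of called segments was unchanged if within 1.5 times the main count, even where other segments were called. Diversity ratios had to stay within 1 SD over draws, and clonotype ratios, sharing and read-weighted CDR3 values within their interval. Other CDR3 values had to stay on the same side of their threshold. A change of direction counted as unchanged where neither value was past its threshold. For the KO to WT ratio of productive clonotypes in spleen CD8, 0.158 became 0.166 with amino acid clonotypes; at equal depth 0.151 became 0.158 with amino acid clonotypes, 0.172 in the smaller draw and 0.149 among standard CDR3s. The ratio of inverse Simpson indices, 0.00823, became 0.0085 with at least 2 reads, 0.00917 with amino acid clonotypes and 0.0124 in the smaller draw. With reads as weights, where a few clones decide a share and no interval applies, the number of called TRBV segments went from 5 to 26 for spleen CD8 KO against WT, from 3 to 13 for lung against spleen CD4 and from 2 to 16 for Treg against CD4, and that of TRBJ segments from 2 to 10, from 6 to 11 and, in lung, from 1 to 6. Of the 35 segments named as called, 22 kept their call with reads as weights and 8 turned: TRBV22 (0.576) and TRBJ1-1 (0.494) in KO against WT CD8, TRBV12-1 (0.463), TRBV13-1 (0.545), TRBJ1-1 (0.655), TRBJ1-4 (1.14) and TRBJ2-4 (1.54) in CD8 against CD4, and TRBV12-1 (2.05) in lung against spleen. With at least 2 reads 33 of the 35 kept their call, at equal depth 31, and among standard CDR3s 29 of 34, TRBV26 having none. For KO against WT CD8, again counted over all segments, called TRBV segments numbered 3 at equal depth, of which 2 were among the 5. Among standard CDR3s there was 1. With at least 2 reads they were again 5, but 3 were the same segments. Called TRBJ segments numbered 0 in lung among standard CDR3s and 6 in Treg with at least 2 reads. The length difference of KO and WT CD8 (0.199) was 0.0641 with at least 2 reads, 0.046 at equal depth, -0.103 among standard CDR3s and -0.331 with reads as weights; that of CD8 and CD4 cleared 0 at equal depth with -0.547 and was 0.15 among standard CDR3s; that of lung and spleen was 0.47 with reads as weights; that of Treg and CD4 (0.461) was 0.24 at equal depth with an interval across 0. The ratio of hydrophobic pairs was 0.088 for KO against WT CD8 and 0.261 for CD8 against CD4 with reads as weights, and as mean hydropathy the first difference was -0.0295 with an interval across 0. The cysteine ratio with reads as weights was 1.9 for KO against WT CD8, 0.591 in lung and 0.543 in Treg, and in the middle of standard CDR3s 3.07 for KO against WT CD8, 2.57 for CD8 against CD4 and 1.07 for Treg against CD4, the last 2 on the other side of 1 from the main values with intervals across 1. The charge difference of CD8 and CD4 was 0.0295 among standard CDR3s and 0.0234 with reads as weights, that of lung and spleen -0.112 with reads as weights, and that of Treg and CD4 cleared 0 at 0.0804 with at least 2 reads, 0.071 at equal depth and 0.0526 among standard CDR3s. Sharing in mouse 617 (72.4) was 84.5 by nucleotide sequence alone. With at least 10 reads in both libraries it was 97.8, extrapolated past the number of clonotypes left. The nonproductive ratio of KO to WT CD8 (1.78) was 2.06 with at least 2 reads and 1.5 without sequences that hold the germline stretch. Rare features rest on few clonotypes in the KO libraries, 12 to 47 for hydrophobic pairs and 3 to 12 for cysteine in the middle of standard CDR3s.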

Other observations

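CDR3s starting CAW, counted over standard CDR3s under any segment name, were a feature chosen after their values were seen, and their share was lower in the 2 CD8 libraries than in the other 3. They made up 1.85% (1.65 to 2.07) of clonotypes in WT spleen CD8 and 2.16% (1.62 to 2.8) in KO spleen CD8, against 7.4% (6.16 to 8.79) in KO spleen CD4, 7.31% (6.42 to 8.28) in KO lung CD4 and 7.84% (6.97 to 8.78) in KO thymus Treg. The ratio of KO spleen CD8 to CD4 was 0.291 (0.213 to 0.4), and the ratios of lung and Treg to spleen CD4 were 0.988 (0.799 to 1.22) and 1.06 (0.862 to 1.3).

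Junctions of KO thymus Tregs held more inserted bases than those of the other libraries, with a mean of 2.61 (2.52 to 2.69) against 1.65 in WT CD8, 1.52 in KO CD8, 1.57 in KO spleen CD4 and 1.65 in KO lung CD4. Standard CDR3s with no inserted base made up 23.4% (22.0 to 24.9) in Tregs and 42.2% to 48.4% in the others. The hypothesis that these bases account for the longer Treg CDR3s was tested at equal numbers of inserted bases, where the Treg excess over spleen CD4 cells was still 0.403 residues (0.324 to 0.484) of 0.481. At equal numbers of listed inserted bases most of the length difference thus remained. Trimming of the segment ends and the share of clonotypes with no D segment listed were not held equal. How much of the length difference the 1.03 more inserted bases of Tregs account for was thus not settled. Lineage, organ and mouse stay open.

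A further hypothesis was that rearrangements with few inserted bases recur in different mice. Among standard CDR3s of KO spleen CD8, the 318 also found in the WT spleen CD8 library held a mean of 0.95 inserted bases and the other 2187 held 1.6, a difference of -0.65 (-0.814 to -0.45). The direction was the one predicted. Clonotypes found in 4 libraries with many reads in the KO CD8 library were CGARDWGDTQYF (TRBV20, TRBJ2-5), with 2612 reads there and 44 in WT CD8, and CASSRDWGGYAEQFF (TRBV17, TRBJ2-1), with 1734 and 130.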
